A study of Homo sapiens with 12 samples.

How the data were processed

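Total RNA of stable HEK cell lines was measured on Affymetrix arrays, 1 array per sample. The samples form 4 groups of 3 arrays (WT untreated, WT with tetracycline, mutant untreated and mutant with tetracycline). Per the labels' protocols, cells grew with 5 ug/mL blasticidin, tetracycline was given for 72 hours, RNA was extracted with Trizol and labelled with biotin, and arrays were processed by the maker's standard protocols. The deposited values are the MAS5 signal of each probe set, an intensity on a linear scale, per the submitters' processing notes. The version and settings of MAS5 are not stated. The mean of each array after trimming 2% at each end was the same on all 12 arrays, about 500, so the values had been scaled per array by the authors to a common mean and not normalized further between arrays.

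Signals under 1, which were 2211 values or 0.337% of the table, were set to 1, and log2 was taken. The table held 54675 probe sets, of which 62 AFFX controls were kept out of the tests. A probe set was tested if its highest group mean was above the median of all values, 6.39 on the log2 scale, which left 29553. By the platform annotation 41097 probe sets carried 1 gene symbol, 1801 carried several and 11721 carried none, and 25072 tested probe sets carried 1 symbol. The table covered 19774 genes, and 13066 had a tested representative, which was the probe set of the gene with the highest mean signal over all 12 arrays. Genomic positions were not used here, and 0 columns of the table were left out.

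All 12 arrays entered 1 linear model with a mean per group, fitted with limma 3.58.1 in R 4.3.3 with eBayes and a trend of the variance on mean signal. The contrasts taken from it were the WT induction, the mutant induction, their difference, the untreated lines and the lines with tetracycline. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05, 2-sided, within each contrast. Replicate numbers were not treated as pairs. Signs of RNA quality were compared with exact permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

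The 31 gene lists, the named-gene rule, the contrasts, the filter and the first alternatives were fixed before the data were examined. The lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, with 1 probe set per gene and the adjustment over lists within a contrast. Members were counted past the threshold over all tested probe sets and adjusted over the list alone. Named genes were the 10 largest rises and 10 largest falls among called probe sets with 1 symbol whose groups did not overlap, for each induction and the difference (where a gap in 1 line was enough), and 6 and 6 for each comparison of lines. Where fewer than 5 passed, the 10 with the smallest p were named. For each list up to 4 members with the smallest p could be named, and near misses were named with their values. The difference had 19 genes by this rule. The genes called with array weights in the mutant line were named because their count was small, after their values were seen.

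The fit was tested on simulated data made of the same size, with known changes in 67, 67 and 66 of 29553 probe sets at log2 sizes of 0.5, 1 and 2. At these sizes it recovered 1.49%, 32.8% and 80.3% for the WT induction, 4.48%, 35.8% and 77.3% for the mutant induction and 2.99%, 7.46% and 62.1% for the difference, with 3.8%, 9.3% and 4% of calls false. A simulated list of 20 genes shifted by 0.5 ranked 1 of 20 with camera, and 0 other lists passed. The noise was drawn independently for each gene, with 1 spread per probe set for all 4 groups. In the data the WT line was noisier, and lists had estimated correlations up to 0.364. For the mutant induction 5.3% of unchanged simulated probe sets had an unadjusted limma p under 0.05, against 2.1% of the real ones. These rates therefore do not describe the fit under the real spread. The comparisons between lines use the same model and group sizes and had no simulation of their own.

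The alternatives were no filter (54613 probe sets), a stricter filter at the 75th percentile of all values, 8.92 (15346 probe sets), an offset of 16 before log2, quantile normalization, eBayes without trend, a fit of only the arrays of the groups compared, a replicate block, leaving out each array in turn, and for lists the estimated correlation and the mean of all probe sets per gene. Added after the data were seen were leaving out the replicate 3 arrays of all groups, whose poly-A control signals were the lowest of each group, a processing block of replicate 3 against the others, and limma array weights.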

Results

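Gene expression was measured on 12 Affymetrix arrays of total RNA from stable lines of HEK cells, a human embryonic kidney cell line, in which tetracycline switches on a TRPM7 transgene. TRPM7 is a membrane protein that joins a channel for magnesium, calcium and zinc to a kinase. One line carried the wild-type channel (the WT line). The other carried a channel without its kinase domain (the mutant line), which the series design names as a nonfunctional control for the inducer. Each line was labelled as untreated or as given tetracycline for 72 hours, which made 4 groups with 3 arrays in each. The labels give the amount of tetracycline as 1 ug without a volume. The values were MAS5 signals, a fluorescence intensity per probe set (a set of short probes for 1 transcript), scaled to the same trimmed mean on every array. After a filter on dim signals 29553 of 54675 probe sets were tested, and 13066 genes had a tested representative. Changes are log2 fold changes with the standard error (SE) of the limma fit and n = 3 arrays per group, and groups are named as labelled. The number of arrays limits the precision. The labels do not say whether the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples.

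The lines differed in signs of RNA quality, and the treatments within a line did not pass a test. The log2 ratio of the 3′ to the 5′ beta-actin control signal was 1.051 ± 0.26 (SD, n = 6) in the WT line and 0.2587 ± 0.026 (SD, n = 6) in the mutant line (2-sided exact permutation p = 0.00216, the smallest possible). The 18S ribosomal RNA control signal was 8.734 ± 0.71 against 6.947 ± 0.55 on the log2 scale (exact p = 0.00216). The GAPDH ratio gave an exact p of 0.779. Between treated and untreated arrays the actin ratio gave an exact p of 0.6 in the WT line and 0.5 in the mutant line, where 0.1 is the smallest possible with 3 against 3. These quality tests were not adjusted for their number. The replicate spread was also wider in the WT line, with a median SD per probe set of 0.299 untreated and 0.326 with tetracycline, against 0.174 and 0.19 in the mutant line. The fit takes 1 spread per probe set over all 4 groups. Its SEs and p-values therefore tend to be too small for the WT induction and too large for the mutant induction.

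**Figure D1:**
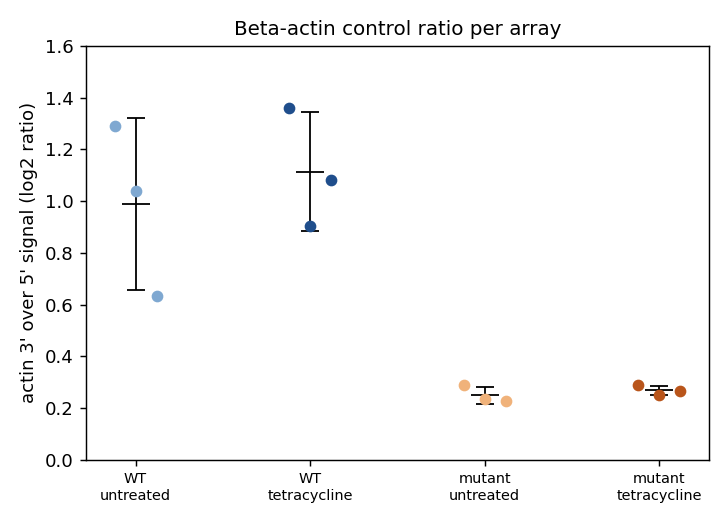
The log2 ratio of the 3′ to the 5′ beta-actin control signal on each of the 12 arrays (points), by group, with the mean and SD of each group. All WT line arrays lie above all mutant line arrays, with means of 1.051 and 0.2587.

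TRPM7, the gene that the transgene carries, had no tested probe set that rose past the threshold on the arrays labelled with tetracycline. Its brightest probe set read 8.47 ± 0.31 (SD, n = 3) untreated and 7.62 ± 0.67 with tetracycline in the WT line, a change of -0.845 ± 0.297 (SE, adjusted p = 0.0643). In the mutant line it read 8.39 ± 0.12 and 8.19 ± 0.3, a change of -0.203 ± 0.297 (adjusted p = 1). The difference between those changes was -0.642 (adjusted p = 0.516). Without WT tetracycline replicate 1 the WT change became -1.13 (adjusted p = 0.00908), without WT untreated replicate 2 it became -1.02 (adjusted p = 0.0451), and without WT tetracycline replicate 3 it became -0.475 (adjusted p = 0.259). With a replicate block the WT change stayed -0.845 and passed (adjusted p = 0.0377). With array weights, chosen after the data were seen, it was -0.893 (adjusted p = 0.0427), and without the replicate 3 arrays -0.409 (adjusted p = 0.507). A dimmer TRPM7 probe set fell in the WT line, by 2.0 ± 0.629 (SE, adjusted p = 0.0411), and another gave 0.113 ± 0.568 (adjusted p = 0.915). In the mutant line they gave -1.24 and -0.805 and did not pass. Of the probe sets too dim to be tested, 1 read 3.97 ± 1.6 (SD) untreated and 5.47 ± 0.77 with tetracycline in the mutant line, but was lower with tetracycline in the WT line. The other was lower with tetracycline in both lines. Where the probes lie relative to the transgene was not analysed here. These signals therefore do not check the tetracycline labels, and every direction of an induction below rests on the labels as given.

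The comparison of treated with untreated WT line arrays asks what the inducer together with the functional channel changed in these cells. Overexpression of this channel damages the cells according to the series design. In the arrays labelled with tetracycline 16 of 25 genes of the integrated stress response rose and 0 fell (camera adjusted p = 1.03e-09, and adjusted p = 0.136 with an estimated correlation). The stress transcription factors ATF3 and DDIT3 rose by 2.03 ± 0.178 and 2.06 ± 0.191 (SE, n = 3 against 3, adjusted p = 6.34e-05 for both), and asparagine synthetase, ASNS, rose by 1.04 ± 0.128 (adjusted p = 0.000274). The cell cycle inhibitor CDKN1A rose by 1.48 ± 0.181 (adjusted p = 0.000266), and the ferritin light chain FTL, an iron store, doubled with 1.00 ± 0.0908 (adjusted p = 6.34e-05). The growth regulator MYC fell by 1.41 ± 0.225 (adjusted p = 0.00112), and lanosterol synthase, LSS, an enzyme of cholesterol synthesis, fell by 1.54 ± 0.231 (adjusted p = 0.000779) while another LSS probe set passed in the opposite direction. MYOM2, a structural protein of muscle, fell by 2.57 ± 0.228 (adjusted p = 6.34e-05).

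In the WT line 5005 of 29553 probe sets passed an adjusted p of 0.05, of which 2313 rose and 2692 fell, and they covered 3354 genes. Of these, 908 rose and 1193 fell by at least 2-fold. The count was 1223 when only the 6 WT line arrays entered the fit, which then takes the spread of that line alone. The smallest adjusted p was 0.0089 there, against 3.08e-05 with all groups. In the fit of all groups the count was 2744 without WT tetracycline replicate 2, 2842 without tetracycline replicate 3, 3295 without untreated replicate 3 and 8077 without tetracycline replicate 1. That last array lay closest to the untreated arrays, at 0.398 of the way from the untreated to the treated mean against 1.03 and 1.1 for tetracycline replicates 2 and 3 (medians over the genes called without the array measured), while the 16 called genes of the integrated stress response lay at a median of 1.18 on it. With the replicate 3 arrays of all groups left out, a choice made after the data were seen, the count was 541. For this comparison 112 called genes were followed through the alternatives, not all of them named here, and 78 of these did not pass without those arrays.

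The 10 genes with the largest rise were H2BC11, LOC100422526, ITGB1BP2, LAMB3, IFI27, AGER, YPEL4, C1QTNF2, SV2C and ASGR1. The histone gene H2BC11 rose by 5.55 ± 0.845 (adjusted p = 0.000833), LAMB3, a chain of a basement membrane laminin, by 4.37 ± 0.531 (adjusted p = 0.000265) and the interferon-induced IFI27 by 4.0 ± 0.428 (adjusted p = 0.000144). The 10 with the largest fall were ZNF287, RAB11B-AS1, PYCR3, MNX1-AS1, WFDC8, EPHX2, MYOM2, NPR1, LYRM7 and MED14OS. PYCR3, an enzyme of proline synthesis, fell by 2.89 ± 0.361 (adjusted p = 0.00028) and NPR1, a receptor for natriuretic peptides, by 2.56 ± 0.316 (adjusted p = 0.000272). The other tested probe set of NPR1 and that of RAB11B-AS1 did not pass. Of these 20 genes, all but MYOM2 and LYRM7 had a group mean below the median of all values, 6.39 on the log2 scale, so their folds rest on dim signals. AGER lost its call without WT tetracycline replicate 3 (adjusted p = 0.0534), EPHX2 without untreated replicate 1 (0.059) or 3 (0.0715), MED14OS without untreated replicate 2 (0.0846) or 3 (0.0971) or tetracycline replicate 3 (0.105), and WFDC8 without any one of 5 arrays of the line, all but tetracycline replicate 3 (0.0626 to 0.107). With the 6 WT line arrays alone these 4 and ASGR1, SV2C, ZNF287 and MNX1-AS1 did not pass.

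**Figure D2:**
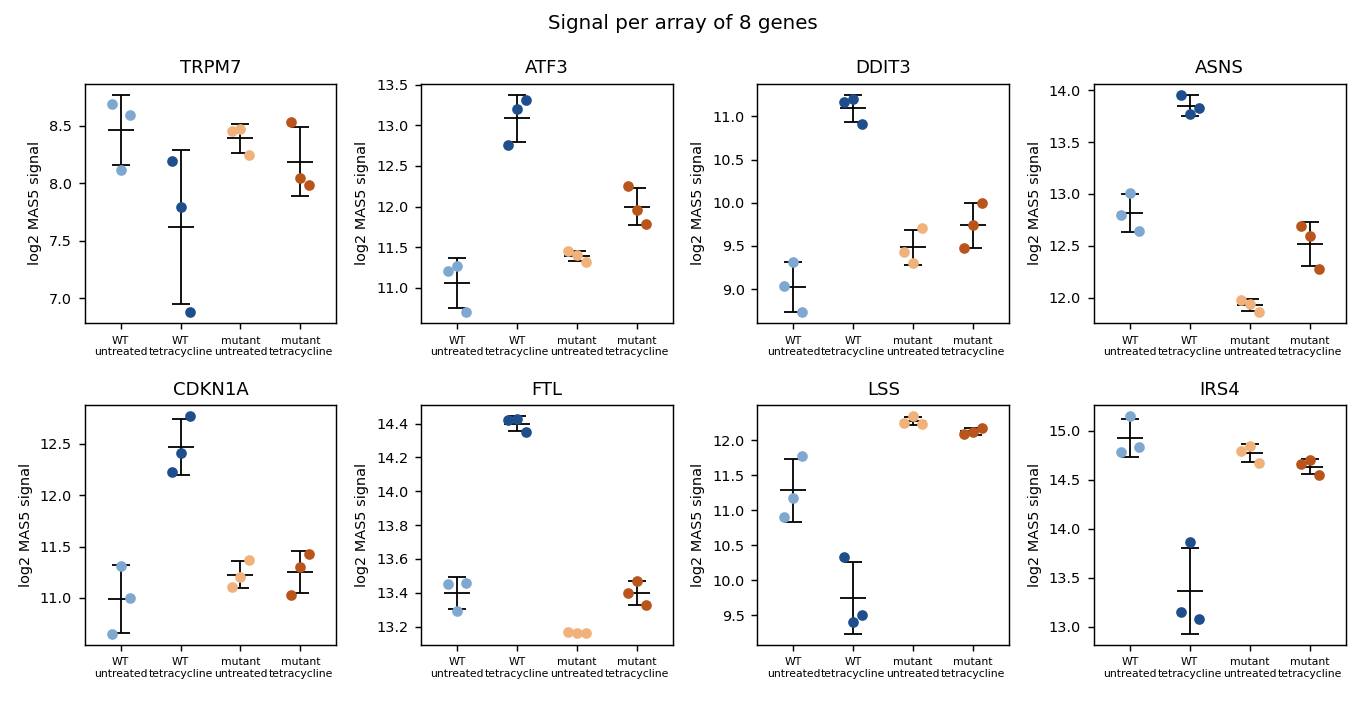
The log2 MAS5 signal of TRPM7, ATF3, DDIT3, ASNS, CDKN1A, FTL, LSS and IRS4 on each array (points), by group, with the mean and SD of each group of 3. ATF3, DDIT3, ASNS, CDKN1A and FTL were higher, and LSS and IRS4 lower, on the WT line arrays with tetracycline than on the untreated ones, while TRPM7 did not rise.

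Of the 31 gene lists, 10 passed camera with its preset correlation in the WT line and 0 with an estimated one. The counts of risen and fallen members come from the fit of all groups, whose p-values tend to be too small for this line. With the WT line arrays alone 53 of the 112 called genes followed, list members among them, did not pass. The list of ATF4 targets and the integrated stress response shifted up, with 16 of 25 members risen and 0 fallen, 17 and 0 adjusted over the list alone (adjusted p = 1.03e-09, and adjusted p = 0.136 with an estimated correlation). CTH, an enzyme of cysteine synthesis, was among them with 1.6 ± 0.183. Of the immediate early genes 8 of 19 rose and 1 fell, 12 and 1 adjusted over the list alone (adjusted p = 4.51e-05, and adjusted p = 0.351 with an estimated correlation). They included CCN1, a secreted matrix protein, with 1.93 ± 0.266 and the transcription factor KLF4 with 1.09 ± 0.183. Of the unfolded protein response 7 of 18 rose and 0 fell, 7 and 0 adjusted over the list alone (adjusted p = 0.000441, and adjusted p = 0.291 with an estimated correlation). XBP1 rose by 1.04 ± 0.129, HERPUD1 by 1.08 ± 0.145 and the stress sensor ERN1 by 1.13.

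More lists that shifted up held p53 targets and lysosomal, histone and MAPK feedback genes. Of the p53 targets 5 of 18 rose and 0 fell, 5 and 1 adjusted over the list alone (adjusted p = 0.0122, and adjusted p = 0.155 with an estimated correlation). GADD45A rose by 1.49 ± 0.22 and GDF15 by 1.73 ± 0.323. Of autophagy and lysosome genes 8 of 20 rose and 0 fell, 9 and 1 adjusted over the list alone (adjusted p = 0.00623, and adjusted p = 0.136 with an estimated correlation). The lysosomal cholesterol transporter NPC1 rose by 0.962 ± 0.154. With the mean of all probe sets per gene this list had an adjusted p of 0.0798. Of the histone list 4 of 7 rose and 0 fell, 5 and 0 adjusted over the list alone (adjusted p = 0.000763, and adjusted p = 0.309 with an estimated correlation). H2BC12 rose by 1.76 ± 0.243 and H2BC5 by 1.81. Only 7 of the 14 genes written for this list matched a probe set. Before induction the list was lower in the WT line than in the mutant line, with a median difference of -1.04. Of the MAPK feedback genes 4 of 15 rose and 0 fell, 6 and 0 adjusted over the list alone (adjusted p = 0.0347, and adjusted p = 0.351 with an estimated correlation), with the phosphatase gene DUSP8 at 1.15.

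Lists that shifted down held genes for protein synthesis in mitochondria, ribosome assembly and cholesterol synthesis. Of the mitochondrial ribosome and translation list 0 of 21 members rose and 8 fell, 10 adjusted over the list alone (adjusted p = 1.41e-05, and adjusted p = 0.291 with an estimated correlation). The mitochondrial elongation factors TSFM and GFM1 fell by 0.832 ± 0.137 and 0.743. Of ribosome biogenesis genes 0 of 19 rose and 6 fell, 9 adjusted over the list alone (adjusted p = 0.00126, and adjusted p = 0.386 with an estimated correlation). RRP9, which acts in ribosomal RNA processing, fell by 1.01 ± 0.215 and did not pass with the 6 WT line arrays alone (adjusted p = 0.076). Of the cholesterol synthesis and SREBP targets 0 of 24 rose and 4 fell, 7 adjusted over the list alone (adjusted p = 0.000441, and adjusted p = 0.386 with an estimated correlation). NSDHL, another enzyme of this pathway, fell by 1.21 ± 0.234 and ACLY, which makes cytosolic acetyl-CoA, by 0.657.

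The other 21 lists did not pass (adjusted p from 0.0631 to 0.986), although single members did. With the mean of all probe sets per gene the matrix (adjusted p = 0.00123), actin (0.0389) and neuronal lists (0.0419) passed as shifted up. In the mitotic cell cycle list 6 of 27 rose and 1 fell, with the proliferation marker MKI67 at 1.08 ± 0.171, and in the DNA replication list 3 of 24 rose and 4 fell. In the actin, myosin and adhesion list 6 of 22 rose and 1 fell, with ANXA1, an annexin, at 1.55 ± 0.206. In the extracellular matrix and TGF-beta list 4 of 18 rose and 1 fell, with the protease inhibitor TIMP1 at 1.11 ± 0.13. In the NRF2 list 3 of 16 rose and 1 fell, with heme oxygenase, HMOX1, at 2.15 ± 0.307 and PGD, an enzyme of the pentose phosphate pathway, at -0.80. In the zinc and metal list 2 of 16 rose and 0 fell. Of the heat shock proteins 2 of 12 rose and 3 fell, with the small chaperone HSPB8 at 2.42 ± 0.303 and the co-chaperone DNAJB1 at -0.911. In the PI3K, insulin and FOXO list 5 of 18 rose and 1 fell, which was IGFBP5, a protein that binds insulin-like growth factors, at -1.36 ± 0.22. Adjusted over the list alone, risen and fallen members were 6 and 2 for the mitotic, 3 and 5 for the DNA replication, 7 and 1 for the matrix and 3 and 5 for the heat shock list, and the counts above for the other lists of this paragraph.

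The remaining lists covered channels, metabolism, stress of mitochondria and tissue markers. Of the channel-kinases and magnesium transport genes 0 of 14 rose and 1 fell, which was the magnesium transport gene MAGT1 at -0.564 (adjusted p = 0.0322). That call was lost without WT untreated replicate 1 (adjusted p = 0.107) or 3 (0.0761) or tetracycline replicate 2 (0.143) or 3 (0.1). It was also lost with the WT line arrays alone (adjusted p = 0.115). Of the TRP and store-operated calcium channels 1 of 13 rose, and of the calcium pumps, stores and calcium binding genes 2 of 14 rose, with none fallen in either. The neuronal list had 4 of 18 risen and 1 fallen, with MAP2, a protein of neuronal microtubules, at 1.5 ± 0.225. The kidney epithelial list had 0 of 13 risen and 1 fallen, and the interferon list 5 of 19 risen and 2 fallen. In the cell death list 2 of 21 rose, in the list of mitochondrial stress and proteases 4 of 17 rose and 4 fell, and in glycolysis and hypoxia 4 of 29 rose and 2 fell. Of nuclear-encoded oxidative phosphorylation genes 2 of 29 rose and 1 fell, and of the NF-kB and cytokine genes 0 of 14 passed. Of the markers of other cell types, 0 of 2 tested blood and immune genes and 1 of 5 fibroblast and endothelial genes passed. Adjusted over the list alone, risen and fallen members were 0 and 0 for the magnesium, kidney and oxidative phosphorylation lists, 3 and 1 for the calcium binding, 6 and 4 for the interferon and 5 and 6 for the mitochondrial stress list, and the counts above for the other lists of this paragraph. Median, mean and test differed in sign for the TRP, heat shock, oxidative phosphorylation, mitochondrial stress, glycolysis, interferon and kidney lists, with a median of 0.126 and a mean of -0.195 for the TRP list tested as shifted down.

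**Figure D3:**
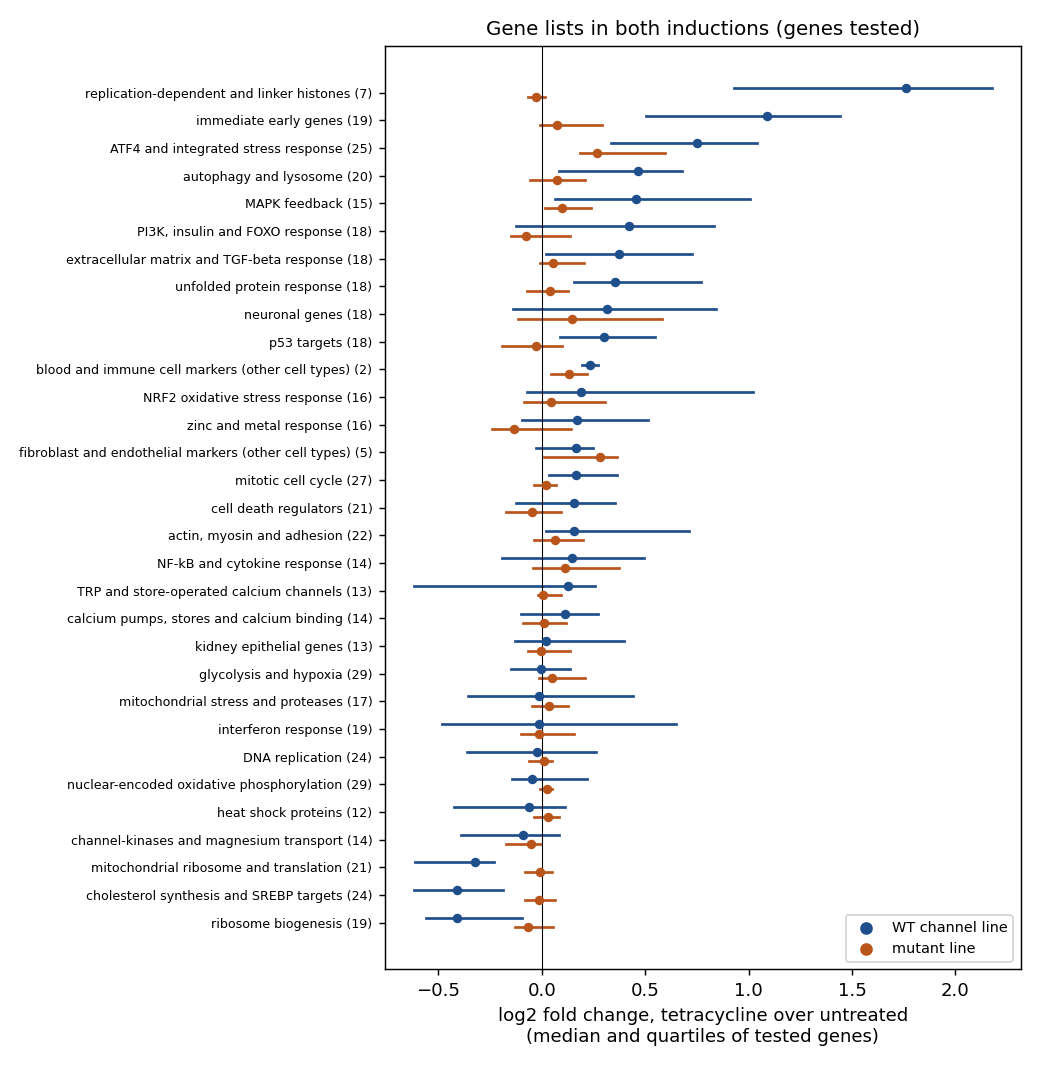
Median and quartiles of the log2 fold change of the tested members of the 31 gene lists on the arrays with tetracycline against untreated arrays, in the WT line (blue) and in the mutant line (orange). The list of the integrated stress response had a median of 0.75 in the WT line and 0.267 in the mutant line.

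In the mutant line, which asks what the inducer and a channel without its kinase changed, no single gene passed, and the integrated stress response genes shifted up together. The median of the 25 list members was 0.267 (camera adjusted p = 4.27e-17, and adjusted p = 0.0488 with an estimated correlation), with 0 past over all probe sets and 6 higher adjusted over the list alone. ASNS changed by 0.596 ± 0.128, CTH by 0.812 ± 0.183 and ATF3 by 0.611 ± 0.178 (SE, n = 3 against 3, adjusted p = 1 each). None of the other 30 lists passed, and 1 neuronal gene passed adjusted over the list alone. The 10 genes with the smallest p, none past the threshold, were EMP3, ASNS, CTH, MAP2, KIR3DX1, FUT1, TNFRSF12A, FAM131B-AS2, HPSE and HDAC5. EMP3, a membrane protein, changed by 0.945 ± 0.192, MAP2 by 0.968 ± 0.225 and TNFRSF12A, a receptor of the tumour necrosis factor family, by 1.03 ± 0.272.

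By limma 0 of 29553 probe sets passed in the mutant line with a smallest adjusted p of 1, and 620 (2.1%) had an unadjusted p under 0.05. Without any change 5% would be expected, so this test, which shares its spread with the noisier WT line, was too strict for the mutant line. The lack of calls does not show that the mutant line had no response. A fit of the 6 mutant line arrays alone also called 0, with 2209 (7.47%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.0616. With array weights, added after the data were seen, 4 probe sets passed. They were those of PPP1R15A, a regulator of the same stress response, at 1.02 (adjusted p = 0.0152), EMP3 at 0.942 (0.0253), ASNS at 0.622 (0.034) and CTH at 0.83 (0.034).

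The test of the difference between the inductions asks what the WT line changed beyond the control line, and is the main comparison of the design. Only a single line carried each channel, and 3807 probe sets differed between the untreated lines. An effect of the channel or its kinase therefore cannot be told apart here from another difference between the lines. The p-values measure only the spread between arrays of these lines. DDIT3 rose by 2.06 in the WT line and gave 0.259 in the mutant line, a difference of 1.81 ± 0.27 (SE, adjusted p = 0.0329). ATF3 differed by 1.42 ± 0.251 (adjusted p = 0.0485), CDKN1A by 1.45 ± 0.256 (adjusted p = 0.0485) and FTL by 0.763 ± 0.128 (adjusted p = 0.0407). LGALS1, a galectin, differed by 1.89 ± 0.272 (adjusted p = 0.0329), with 2.08 in the WT line and 0.186 in the mutant line. Among bright genes with a lower change in the WT line, the insulin receptor substrate IRS4 differed by -1.42 ± 0.236 (adjusted p = 0.0405), the chromatin protein PSIP1 by -1.35 ± 0.182 (adjusted p = 0.0329) and MYOM2 by -2.27 ± 0.322 (adjusted p = 0.0329).

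In all, 41 probe sets of 37 genes passed for the difference, 19 with a higher and 22 with a lower change in the WT line, and 4271 (14.5%) had an unadjusted p under 0.05. All 41 were also called with the same sign in the WT induction, which uses the same WT line arrays. The other genes named by the rule were IFI27 with 3.73, LSMEM1 with 3.19, SCARA5 with 2.55, the transcription factor NFIL3 with 1.29 and GFPT1, which opens hexosamine synthesis, with 1.20. On the lower side they were NPR1 with -2.98, PYCR3 with -2.79, OGFOD3 with -2.36, L3HYPDH with -1.98, CYP4X1 with -1.85 and NDUFA7, a subunit of respiratory complex I, with -1.05. ATF3, FTL, LSMEM1, SCARA5, NPR1, OGFOD3, IRS4, PSIP1 and NDUFA7 each had 1 or 2 other tested probe sets, none of which passed. For GFPT1 1 of 3 others passed with the same sign. The count was 0 without any one of the 6 mutant line arrays or without WT tetracycline replicate 3. It was 1 without WT untreated replicate 3, 7 without WT tetracycline replicate 2 and 2702, including all 41, without WT tetracycline replicate 1, so every gene named here lost its call when at least 1 single array was left out. The count was also 8 without the filter, 6 without the variance trend, 15 with quantile normalization, 76 with an offset of 16, 76 with a replicate block and 89 with the stricter filter. By alternatives chosen after the data were seen, it was 0 without the replicate 3 arrays, 27 with a processing block and 2493 with array weights.

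**Figure D4:**
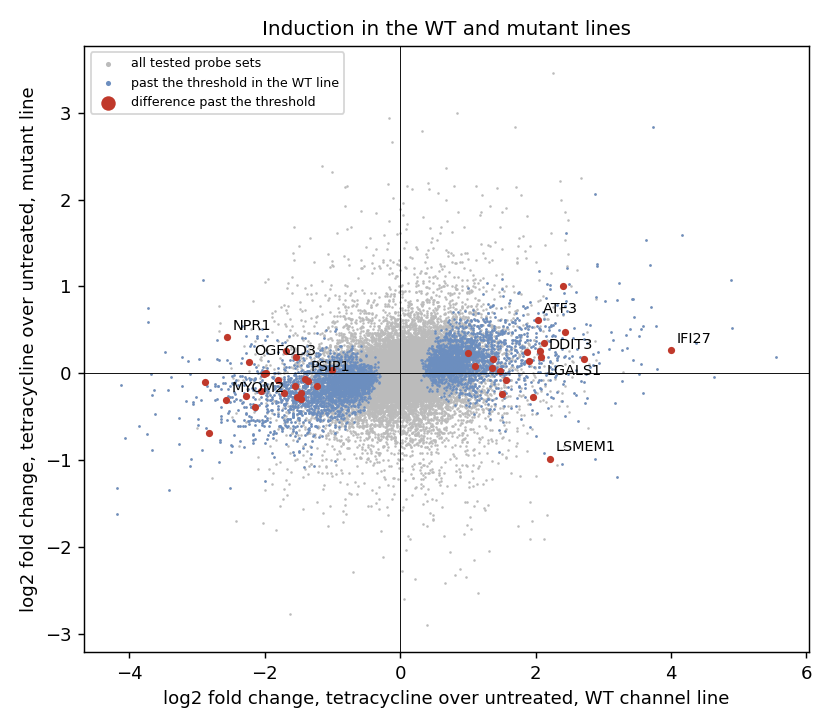
Log2 fold change with tetracycline in the WT line (x axis) against that in the mutant line (y axis) for tested probe sets (grey), with those past the threshold in the WT line in blue and the 41 past the threshold for the difference in red. The 41 lie far from 0 on the x axis and closer to 0 on the y axis.

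Of the 31 lists, 10 passed for the difference with the preset correlation and 0 with an estimated one. Changes were higher in the WT line for the integrated stress response (median 0.441, adjusted p = 3.1e-05, and adjusted p = 0.226 with an estimated correlation), with 2 members past and 5 adjusted over the list alone. For the immediate early genes the median was 1.06 (adjusted p = 5.57e-05, and adjusted p = 0.376 with an estimated correlation), with 1 member past and 8 higher and 1 lower adjusted over the list alone. The unfolded protein response had a median of 0.392 and the histone list 1.58 (adjusted p = 8.69e-05 for both, and adjusted p = 0.226 with an estimated correlation), with 0 members past and 5 and 4 adjusted over the list alone. The p53 targets had a median of 0.492 (adjusted p = 0.000337, and adjusted p = 0.0894 with an estimated correlation), with 1 past and 3 adjusted over the list alone. The autophagy and lysosome list had 0.38 (adjusted p = 0.00767, and adjusted p = 0.159 with an estimated correlation) and the mitotic list 0.146 (adjusted p = 0.0303, and adjusted p = 0.512 with an estimated correlation), each with 0 past and 1 adjusted over the list alone. Changes were lower in the WT line for the mitochondrial ribosome list (median -0.334, adjusted p = 3.1e-05, and adjusted p = 0.233 with an estimated correlation) and the cholesterol list (-0.372, adjusted p = 0.00043, and adjusted p = 0.458 with an estimated correlation), with 0 past and 3 adjusted over the list alone in each. Ribosome biogenesis had a median of -0.344 (adjusted p = 0.00191, and adjusted p = 0.458 with an estimated correlation), with 0 past by either count. With the mean of all probe sets per gene the matrix list also passed for the difference (adjusted p = 0.00484). XBP1 differed by 0.833 (adjusted p = 0.0791), H2BC12 by 1.78 (adjusted p = 0.0569), CCN1 by 1.79 (adjusted p = 0.0708) and LSS by -1.39 (adjusted p = 0.0891), none of which passed. All 4 passed without WT tetracycline replicate 1 (adjusted p from 0.000207 to 0.00667) and with array weights (0.000702 to 0.00824), and H2BC12 passed with the stricter filter (0.0412), with the offset (0.0482) and without WT untreated replicate 2 (0.0405).

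Genes called in the WT line mostly had the same sign of change in the mutant line. Of 2350 genes whose representative probe set was called in the WT line, 1889 (80.4%) had the same sign in the mutant line. The risen genes had a median of 0.823 in the WT line and 0.148 in the mutant line, and the fallen genes -0.80 and -0.0895. Across 13066 genes, which are not independent replicates, the changes had a Pearson r of 0.273 and a Spearman rho of 0.339, and r was 0.0495 without the filter and 0.471 with the stricter one.

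The untreated lines were compared to see how far they differed before induction. SPARC, a secreted matrix protein, was far lower in the WT line, at 1.691 against 11.38 on the log2 scale (difference -9.69 ± 0.526, adjusted p = 4.15e-07). The phospholipase gene PLA2G4A (-5.91), the transcription factor IKZF2 (-5.74), HACD4 (-5.89), ARMCX2 (-4.88 ± 0.697) and the neuropeptide gene NPW (-4.41) were also lower. The lower signals of SPARC, PLA2G4A (1.395), IKZF2 (1.456) and HACD4 (2.356 with an SD of 2.6) lie near the floor, so the sizes of these differences depend on it. The neuronal gene PNMA8A (4.85 ± 0.504), PABPC4L (5.02 ± 0.998), the growth factor gene NRG3 (4.01 ± 0.758), CHSY3 (3.06), SNTG2-AS1 (2.37) and LOC105371763 (2.66) were higher, with dim mutant means of 2.543 (SD 2.3) for PABPC4L and 3.082 for NRG3. LOC105371763 lost its call without any one of the 6 untreated arrays (adjusted p from 0.05 to 0.115).

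In the untreated lines 3807 probe sets passed, 1237 higher and 2570 lower in the WT line, against 1357 and 1782 with quantile normalization, which moved the median of all genes from -0.0916 to 0.0073. The actin ratio moved with the line in this and the next comparison. The cholesterol list was lower in the WT line with 0 of 24 members higher and 7 lower (adjusted p = 0.000105, and adjusted p = 0.436 with an estimated correlation), among them TM7SF2 at -1.53. The interferon list was lower with 0 of 19 higher and 5 lower (adjusted p = 0.00223, and adjusted p = 0.295 with an estimated correlation), among them IFI27 at -3.70 and IFI6 at -1.41. Histones (0 and 2 of 7, adjusted p = 0.0101) and actin, myosin and adhesion genes (0 and 4 of 22, adjusted p = 0.0473) were lower too, both with adjusted p = 0.436 with an estimated correlation. Heat shock proteins were higher with 5 of 12 higher and 0 lower (adjusted p = 0.000165, and adjusted p = 0.0583 with an estimated correlation), among them HSPE1 at 0.727. Higher oxidative phosphorylation (4 and 0 of 29, adjusted p = 0.000105), mitochondrial ribosome (4 and 0 of 21, adjusted p = 0.0101), ribosome biogenesis (4 and 1 of 19, adjusted p = 0.0251) and mitochondrial stress lists (3 and 0 of 17, adjusted p = 0.0436) did not pass with quantile normalization (adjusted p from 0.182 to 0.36) or with an estimated correlation (adjusted p from 0.295 to 0.607). With the mean of all probe sets per gene the matrix list passed as lower (adjusted p = 0.0028). Adjusted over the list alone, higher and lower members were 0 and 11 for cholesterol, 0 and 5 for interferon, 0 and 3 for histones, 1 and 6 for actin, 7 and 0 for heat shock, 8 and 0 for oxidative phosphorylation, 5 and 1 for the mitochondrial ribosome, 7 and 2 for ribosome biogenesis and 4 and 0 for mitochondrial stress. The count of probe sets was 1644, 1621 and 2130 without mutant untreated replicate 1, 2 and 3, and 1717 without all replicate 3 arrays.

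With tetracycline in both lines, the comparison holds the difference between the lines and their responses together. SPARC (-8.37 ± 0.526), ARMCX2 (-7.03 ± 0.697), IKZF2 (-5.74), HACD4 (-5.58), PLA2G4A (-5.31) and PNPLA4 (-4.70) were lower in the WT line, and NRG3 (5.07), PNMA8A (4.51), PABPC4L (4.32), WDR38 (4.30), the transporter gene ABCC2 (3.93) and PCED1B (3.67) were higher. All 12 had a mean in 1 line below the median of all values, 6.39, so these sizes rest on dim signals. Of these, ABCC2 lost its call without any one WT tetracycline array, mutant tetracycline replicate 1 or 3, mutant untreated replicate 1 or 2, or WT untreated replicate 3 (adjusted p from 0.0512 to 0.163), PCED1B without WT tetracycline replicate 2 (0.0815) or 3 (0.0646) or mutant tetracycline replicate 2 (0.0706), and PNPLA4 without WT tetracycline replicate 3 (0.0501). Genes of cholesterol synthesis were lower in 18 of 24 cases and higher in 0 (adjusted p = 2.42e-08, and adjusted p = 0.269 with an estimated correlation). LSS differed by -2.37 ± 0.231, TM7SF2 by -2.21 and NSDHL by -1.77. The integrated stress response was higher, with 9 of 25 higher and 0 lower (adjusted p = 0.00241, and adjusted p = 0.322 with an estimated correlation), among them ASNS at 1.33 ± 0.128 and DDIT3 at 1.35.

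With tetracycline 8151 probe sets passed between the lines, 3024 higher and 5127 lower in the WT line, against 3511 and 4053 with quantile normalization. The unfolded protein response was higher with 8 of 18 higher and 0 lower (adjusted p = 0.00512, and adjusted p = 0.322 with an estimated correlation), and p53 targets with 7 of 18 and 0 (adjusted p = 0.00512, and adjusted p = 0.244 with an estimated correlation), with CDKN1A at 1.21. Immediate early genes were higher with 8 of 19 higher and 1 lower (adjusted p = 0.00421, and adjusted p = 0.494 with an estimated correlation), and MAPK feedback genes with 4 of 15 and 0 (adjusted p = 0.0347, and adjusted p = 0.322 with an estimated correlation). Oxidative phosphorylation (10 and 1 of 29, adjusted p = 0.00241), mitotic (8 and 1 of 27, adjusted p = 0.0213), autophagy and lysosome (6 and 1 of 20, adjusted p = 0.0366) and heat shock lists (5 and 1 of 12, adjusted p = 0.0459) did not pass with quantile normalization (adjusted p from 0.13 to 0.547) or with an estimated correlation (adjusted p from 0.269 to 0.501). With the mean of all probe sets per gene the autophagy (adjusted p = 0.199) and heat shock lists (0.166) did not pass either. Adjusted over the list alone, 0 and 20 members of the cholesterol list and 8 and 1 of the autophagy list were higher and lower, and the other lists named had the counts above. The count of probe sets was 5408 and 5216 without mutant tetracycline replicate 1 and 2, and 2771 without all replicate 3 arrays. The mitochondrial ribosome list passed as lower with quantile normalization alone (adjusted p = 0.0213). Both comparisons between lines called 2432 probe sets, 2421 of them with the same sign, where 1050 would be called in both if the calls were independent. They are not independent, since both comparisons take the same lines and share the spread of each probe set, so 1050 is not a chance level.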

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

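The tests of RNA quality, of an exchange with WT untreated replicate 2 and of a mixture with untreated RNA were chosen after the result was seen.

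A test of the difference between the inductions in the WT and mutant lines (an interaction term) singled out 41 probe sets. Among the genes named, the stress factors DDIT3 (1.81) and ATF3 (1.42), the cell cycle inhibitor CDKN1A (1.45), FTL (0.763), LGALS1 (1.89), NFIL3 (1.29), GFPT1 (1.2), IFI27 (3.73), LSMEM1 (3.19) and SCARA5 (2.55) had a higher log2 change in the WT line. NPR1 (-2.98), PYCR3 (-2.79), OGFOD3 (-2.36), MYOM2 (-2.27), L3HYPDH (-1.98), CYP4X1 (-1.85), IRS4 (-1.42), PSIP1 (-1.35) and NDUFA7 (-1.05) had a lower one. The sizes for IFI27, LSMEM1, NPR1 and PYCR3 rest on dim signals. Over 100 drawn assignments of tetracycline labels within each line, the real one included, 18 gave at least 41 calls and the highest other gave 2467, so this tally does not exclude chance. The assignment with 2467 calls kept the real WT line labels. Of the 18, 12 kept the real WT line labels and with them the WT induction, and all 12 drawn of that kind reached 41 whatever the mutant labels. The tally is therefore not one of samples without a change, and the highest count with other WT labels was 222.

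The array WT tetracycline replicate 1 lay at 0.398 of the way from the untreated to the treated arrays, and the difference count rose to 2702 without it. An equal shift from processing shared with the untreated array of its own number is argued against, since its change measured against that array was 0.432 of that of the others (0.875 and 1.02 for numbers 2 and 3). This ratio cannot see processing that shrinks the changes, which stays open. The 2 WT line arrays numbered 1 had the highest actin ratios of the line (1.29 untreated and 1.36 with tetracycline) and correlated at 0.25 after removal of group means. An exchange of its label with an untreated array is argued against as well, since the highest position of an untreated array was 0.278, that of WT untreated replicate 2. With both arrays left out of the reference, WT untreated replicate 2 lay at 0.29 and WT tetracycline replicate 1 at 0.406, not far apart. A mixture with untreated RNA, or a response short by the same share for every gene, is argued against as the whole cause, since the 16 called genes of the integrated stress response lay at a median of 1.18 (quartiles 0.979 and 1.45, permutation adjusted p = 0.0021 over 21 lists). That p comes from random draws of called genes on this 1 array. It treats the genes as independent and does not measure variation between arrays. Lower RNA quality of that array, whose actin ratio exceeded the highest of the other WT line arrays by 0.07 (SD 0.265), and a response weaker for most but not all genes may remain and stay open, as its median positions for risen and fallen genes (0.468 and 0.338) differed by 0.13.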

How the results depend on the processing

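The tests without the replicate 3 arrays, with a processing block and with array weights were chosen after the data were seen. No called gene named in the text and no called list changed its direction under the alternatives run for it. The lists were run only with the estimated correlation, quantile normalization, the replicate block and the mean of all probe sets per gene. KIR3DX1 in the WT induction, near 0 and not called, was -0.0241 with quantile normalization, -0.0113 without the replicate 3 arrays and -0.319 to 0.311 without 1 array. The count for the difference of inductions, 41, was 8 without the filter, 89 with the stricter filter, 76 with the offset, 15 with quantile normalization, 6 without trend, 76 with the replicate block, 27 with the processing block, 2493 with array weights and 0 without the replicate 3 arrays. Without those arrays the counts were 541 for the WT induction, 1717 for the untreated lines and 2771 for the lines with tetracycline, with fewer arrays in each fit. Of the genes followed through the alternatives, not all of them named here, 78 of 112, 10 of 32 and 8 of 27 lost their call. The WT induction gave 1223 calls with its 6 arrays alone. The mutant induction gave 4 calls with array weights and 0 under every other alternative. TRPM7 in the WT induction kept -0.845 and passed with the replicate block (adjusted p = 0.0377), was -0.893 with array weights (adjusted p = 0.0427), was not measured under the stricter filter, and had adjusted p = 0.0643 as reported. The correlation of the inductions, 0.273, was 0.0495 without the filter and 0.471 with the stricter filter. With an estimated correlation 0 lists passed for the WT induction, 0 for the difference, 0 for the untreated lines, 0 for the lines with tetracycline and 1 for the mutant induction, and with quantile normalization 5 passed for the untreated lines. Leaving out 1 array gave 2744 to 8077 calls for the WT induction (8077 without WT tetracycline replicate 1), 0 to 2702 for the difference, 0 for the mutant induction, 1621 to 5369 for the untreated lines and 5216 to 10245 for the lines with tetracycline. It gave -1.13 to -0.475 for TRPM7 in the WT induction, -0.374 to -0.103 in the mutant induction, 0.223 to 0.279 for the correlation and 73.7% to 85.9% for the share of genes with the same sign. Of the 112 genes followed that were past the threshold in the WT induction, 53 did not pass with the 6 arrays alone and 34 lost the call without at least 1 array. With the replicate block H2BC12 in the difference and HDAC5 in the WT induction passed (adjusted p = 0.0409 and 0.0403), and PYCR3 in the difference (0.0553), ABCC2 in the lines with tetracycline (0.0558) and H2AC6 in the WT induction (0.052) did not. Replicate numbers were not taken as pairs. Arrays with the same number correlated at 0.042 to 0.25 in the WT line and 0.026 to 0.21 in the mutant line after removal of group means, with 9 of 12 arrays correlated best with their own number. The GAPDH ratio was also highest for number 1 and lowest for number 2 in every group. The poly-A control signals were the lowest for number 3 in every group. Arrays of the same number therefore seem to share a part that the main fit does not model, and the results with the replicate block allow for it. For the difference 19 of 19 genes followed lost their call without at least 1 array, for the untreated lines 6 of 32 and for the lines with tetracycline 3 of 27. Of 40 list calls 39 did not pass with an estimated correlation, 8 with quantile normalization, 3 with the mean of all probe sets (autophagy in the WT induction, autophagy and heat shock in the lines with tetracycline) and 1 with the replicate block (actin in the untreated lines, adjusted p = 0.0565). Lists that passed only under an alternative were 5 with the mean of all probe sets (matrix, actin and neuronal genes in the WT induction, and matrix genes in the difference and the untreated lines) and 1 with quantile normalization (the mitochondrial ribosome in the lines with tetracycline, adjusted p = 0.0213). Apart from the smaller fits, the cause was not tested. Signal over background limits dim genes, whose folds depend on values near the floor of 1.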

Other observations

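The tests of scaling and both tests of TRPM7 were chosen after the result was seen.

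Of the 10 genes with the smallest p in the mutant line, 8 passed in the WT line in the same direction. EMP3 rose there by 1.76 ± 0.192 (SE, n = 3 against 3, limma adjusted p = 0.000144), TNFRSF12A by 2.17 ± 0.272 (adjusted p = 0.00028) and HPSE, an enzyme that cleaves heparan sulfate, by 1.28 ± 0.168 (adjusted p = 0.000359). FUT1, also among the 8, rose by 1.0 ± 0.256 and lost its call without WT untreated replicate 1 (adjusted p = 0.0554) or tetracycline replicate 2 (0.054). The FUT1 call was also lost with the WT line arrays alone (adjusted p = 0.0917). In the fit of all groups KIR3DX1 (0.0213) and HDAC5 (0.561, adjusted p = 0.0849) did not pass in the WT line, although HDAC5 did without WT untreated replicate 2 (adjusted p = 0.0338). In the glycolysis and hypoxia list, the neuronal enolase ENO2 rose by 1.49 ± 0.333 in the WT line and P4HA2, a collagen prolyl hydroxylase, by 0.859 ± 0.162. IFI27 rose in the WT line from 3.406 to 7.406 on the log2 scale and read 7.105 and 7.373 in the mutant line, and LAMB3 rose from 3.376 to 7.744 where the mutant line read 7.077 and 7.423.

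Other genes differed between the lines with and without tetracycline. Without it, the aldo-keto reductase AKR1C1 (-1.59 ± 0.328), the keratin KRT8 (-1.14 ± 0.176), the cell death effector BAK1 (-1.11 ± 0.191) and the magnesium transport gene CNNM3 (-1.04 ± 0.17) were lower in the WT line, and the growth factor VEGFA (1.06 ± 0.202) was higher. With it, the values were -1.39, -0.958, -0.847, -0.92 and 1.28, and all of these passed. The interferon list with tetracycline had 0 of 19 members higher and 9 lower, with IFITM1 at -1.46 and IFI6 at -0.815, and the list did not pass (adjusted p = 0.0723).

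Each comparison of 3 with 3 arrays has 10 splits, too few for a share under 0.05. For the WT induction 1 of 10 splits, the real one, gave as many as 5005 calls. The highest other, which exchanged WT tetracycline replicate 1 with WT untreated replicate 2, gave 2618. For the mutant induction 10 of 10 gave 0. For the untreated lines 1 of 10 gave 3807 with a highest other of 0, and for the lines with tetracycline 1 of 10 gave 8151 with a highest other of 0.

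Genes called in the WT induction moved the same way in the mutant line in 80.4% of cases. A difference in scaling between treated and untreated mutant arrays is argued against, since with quantile normalization the genes fallen in the WT line had a median of -0.094 and the risen ones 0.152. For a direction that the mutant arrays took by chance, 1 of 10 splits, the real one, lay as far from an even share, with a highest other of 70.9%, and the splits are too few. A response to tetracycline that both lines share, or a weak effect of the channel without its kinase, may remain and was not tested, since no line without a transgene is among the groups.

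No tested TRPM7 probe set rose past the threshold on the arrays labelled with tetracycline. Probe sets outside the transgene may explain this and stay open, since 1 of 5 TRPM7 probe sets was higher in the WT line and it did not pass. Exchanged treatment labels in the WT line alone stay open too, since the 80.4% of genes with the same sign speaks for the same order of labels in both lines only if both lines answer the inducer alike, which was not tested. An exchange in both lines would leave that share as it is. No biological explanation was tested.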
